A study of Mus musculus with 20 samples.

How the data were processed

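The study measured poly-A RNA of tumour-associated myeloid cells sorted from mice, as 20 libraries in 4 groups of 5, and every library had 1 deposited file. Per the labels, female SCID.beige mice, which lack T, B and functional NK cells, carried subcutaneous tumours of MDA.MB.231-X1.1, derived from a human breast cancer line, or CT26, a mouse colon carcinoma line, and the labels name both without tying a library to either. Dosing with vehicle (MCT) or with 25 mg/kg of GNE-781, an inhibitor of the bromodomains of the histone acetyltransferases CBP and EP300 (here CBPi), ran BID by oral gavage for 7 days from a mean tumour volume of 150 to 200 mm3. Tumours were digested with collagenase D and DNAse, and 2 populations were taken by flow cytometry. Both were positive for CD11b, CD45 and Ly6C and negative for F4/80. The mMDSC lacked Ly6G and the gMDSC carried it. Libraries came from the TruSeq V2 kit.

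Each file held 23090 genes with an Entrez gene ID, a count, a width and an RPKM value. The counts are whole numbers of reads per gene as the authors deposited them, without normalization. The RPKM values, also computed by the authors and deposited beside the counts, were used only to recover the library total behind them, of which the counts made up 50.25% to 62.44%. Per the submitters' processing notes the reads were aligned with GSNAP to GRCm38, with no version named; the counter, its annotation and its treatment of strand are not given in the sources used here. Of the IDs, 21647 matched a symbol in a RefSeq gene table of assembly GRCm38.p6, which also gave the coordinates, and 1443 did not, 588 of them with counts. The counting could not be told apart for near-identical genes: 115 genes with at least 100 counts in all shared identical counts with another gene in all libraries, so members of such families are reported as uncertain, as are overlapping and antisense genes. Widths were multiples of 3 in 79.97% of genes.

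Library totals ran from 12.37 to 26.64 mega-counts (M). No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom at least 21.6), and each was used as 1 replicate. All intervals and errors describe the spread between these libraries. The labels do not say which libraries came from one mouse, so p-values measure the spread between samples, part of which may be technical. Nor do they give the tumour line of a library. Differences between lines, within or between groups, therefore cannot be told apart here.

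Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test (glmQLFit and glmQLFTest), with TMM normalization and filterByExpr (minimum count 10, minimum total 15) on the libraries of each comparison. The Benjamini-Hochberg adjusted p had to be under 0.05. The comparisons were CBPi against vehicle within mMDSC and within gMDSC (10 libraries each), the difference between these responses (interaction, 20 libraries) and gMDSC against mMDSC in vehicle (10 libraries). The standard error of a log2 fold change was its size divided by the square root of F. CPM values are TMM-scaled within the libraries of the comparison, so the levels of one gene differ slightly between comparisons. The 25 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, for lists with at least 5 tested members. Medians of lists are over the edgeR log2 fold changes. The lists, fixed like the tests and most alternatives before the data were examined, held 581 genes, of which 29 were in more than 1 list and 1 had no match. They covered suppressive effectors of myeloid cells, STAT3 targets, hypoxia and glycolysis, type I interferon, interferon-gamma, MHC class II, MHC class I, NF-kB, immediate-early and dissociation stress, cell cycle, MYC and ribosome biogenesis, cholesterol synthesis, lysosome, matrix remodelling and angiogenesis, histone acetyltransferases with deacetylases and BET genes, neutrophil granules, and markers of neutrophils, monocytes, macrophages, dendritic cells, lymphocytes and NK cells, stroma and endothelium, epithelium, erythroid cells and platelets, and mast cells, basophils and eosinophils.

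Named genes followed a rule fixed at that time. Per CBPi comparison it took the 8 largest log2 fold changes in each direction with adjusted p under 0.05 and a mean of at least 10 CPM in 1 group, up to 2 members per list with the smallest p, and 14 fixed genes (Crebbp, Ep300, Arg1, Nos2, Cd274, Myc, Stat3, S100a8, S100a9, Il1b, Tnf, Il6, H2-Ab1 and Cd74). For the interaction and the cell types it took the 5 largest in each direction, with the 14 fixed genes or 12 markers of the gates and cell types. Other list members named as examples were chosen after their values were seen.

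On simulated counts with the real means, totals and dispersions and 200 changed genes, the mMDSC comparison recovered 8.96% of 1.5-fold, 50.7% of 2-fold and 81.8% of 4-fold changes over 11912 genes. The gMDSC comparison recovered 1.49%, 19.4% and 74.2% over 11694 genes, the interaction 1.49%, 20.9% and 57.6% over 12688, and the cell-type comparison 0%, 22.4% and 68.2% over 11576. In these 4 tests 4.08%, 4.55%, 5.36% and 0% of the calls were false. A list raised by 1.5-fold was called in each, and no other list was. Simulated genes varied independently of each other, so this does not measure false list calls among genes that vary together.

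Alternatives were DESeq2 size factors in edgeR, no filter, a stricter filter (5 CPM in 5 libraries), DESeq2 1.42.0, limma voom with sample quality weights, all 20 libraries in 1 fit, a fit without the libraries numbered 3 and 7 of either cell type (in the order of deposit these stand among libraries of the other type), a covariate for the other cell type's identity list, the replicate number as a block, and leaving out each library in turn. Lists were also tested with an estimated correlation and with fry. Added after seeing the data were libraries thinned to the smallest total and a fit without the gMDSC CBPi libraries 6 and 7. For each comparison 100 splits of the same libraries, the real one included, were refitted. The count of splits giving each list a camera p as small as the real one was likewise added afterwards and is not adjusted for the number of lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main comparisons. The value of 1 list member is not reported here.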

Results

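RNA of 2 tumour-associated myeloid populations, called monocytic (mMDSC) and granulocytic (gMDSC) myeloid-derived suppressor cells in the labels, was counted per gene in 20 libraries. There were 5 libraries each of mMDSC and gMDSC from mice dosed with vehicle, and 5 each from mice dosed with GNE-781 (CBPi), an inhibitor of the bromodomains of the acetyltransferases CBP and EP300. Total counts, in mega-counts (M), were 17.79, 23.23, 13.51, 18.41 and 22.53 M in vehicle mMDSC 1 to 5. In CBPi mMDSC 6 to 10 they were 21.03, 22.86, 19.49, 23.71 and 26.64 M. Vehicle gMDSC held 12.46, 12.37, 14.10, 13.65 and 23.27 M counts, and CBPi gMDSC 20.91, 22.43, 20.55, 19.74 and 21.75 M. Correlations of log2 CPM between replicates were 0.928 to 0.964 in vehicle mMDSC, 0.942 to 0.964 in CBPi mMDSC, 0.848 to 0.953 in vehicle gMDSC and 0.932 to 0.956 in CBPi gMDSC. Values are means ± SD in CPM, scaled by TMM, with n = 5 libraries per group, log2 fold changes carry their standard errors, and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Coordinates are of GRCm38.

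**Figure D1:**
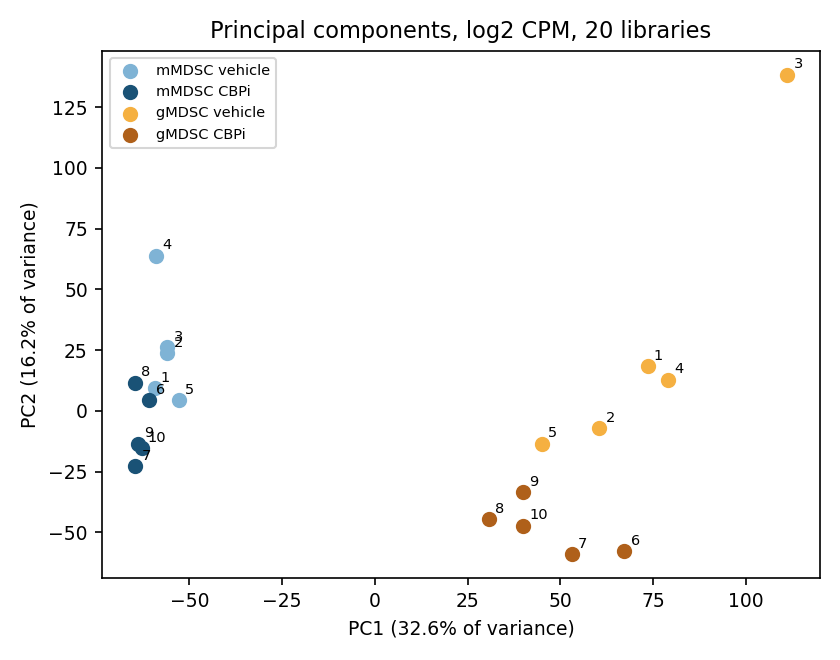
Principal components of log2 CPM over 12688 genes, 1 point per library, with PC1 (32.6% of the variance) on the x axis, PC2 (16.2%) on the y axis and the 4 groups in colour. PC1 separated gMDSC from mMDSC libraries, and vehicle gMDSC 3 lay at 138.3 on PC2 while libraries other than it and vehicle mMDSC 4 (63.9) lay between -58.8 and 26.3.

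The comparison of gMDSC with mMDSC in vehicle mice described the sorted populations without CBPi. The neutrophil chemokine receptor Cxcr2 (GeneID 12765, chromosome 1, 74153994 to 74161246) was at 1.25 ± 0.948 CPM in mMDSC and 1393 ± 335 CPM in gMDSC (log2 fold change 10.17 ± 0.55 (SE), adjusted p = 1.02e-07). The receptor of granulocyte colony-stimulating factor, Csf3r, was higher in gMDSC by 4.08 ± 0.17 (adjusted p = 1.6e-08), and the calcium-binding alarmins S100a8 and S100a9 by 7.78 ± 0.58 (adjusted p = 1.07e-06) and 8.91 ± 0.69 (adjusted p = 1.52e-06). In mMDSC the coagulation factor subunit F13a1 (GeneID 74145, chromosome 13, 36867178 to 37050244) was at 261 ± 71.7 CPM against 2.86 ± 1.65 CPM in gMDSC (log2 fold change -6.47 ± 0.44 (SE), adjusted p = 5.45e-07). The monocyte surface genes Ly6c2 and Ly6c1, close paralogs whose reads may be shared, differed by -4.23 ± 0.35 (adjusted p = 2.89e-06) and -4.25 ± 0.37 (adjusted p = 4.39e-06), and the chemokine receptor Ccr2 by -1.56 ± 0.28 (adjusted p = 0.00144).

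Of 11576 genes tested, 1579 were higher and 935 lower in gMDSC, and 3780 had an unadjusted p under 0.05. The largest differences with at least 10 CPM in a group were, higher in gMDSC, the interleukin-36 cytokine Il1f9 (10.30), Cxcr2, Rufy4 (10.16), GeneID:404236 (9.97) and Amer2 (9.95), and, lower, the phospholipase Plcb1 (-7.08), the calcium-binding S100a4 (-6.61), F13a1, and the type I interferons Ifna5 (-6.43) and Ifna4 (-6.26), members of a family of near-identical genes. Ifna5 had counts in vehicle gMDSC 4 alone of the vehicle gMDSC libraries, and without that library its value was -10.56. All 10 separated the groups without overlap, as did 2323 genes in all (20.1%, where chance gives 0.794%). Of the other marker genes, the pan-leukocyte Ptprc (CD45) was at 0.34 ± 0.15 (adjusted p = 0.131), Adgre1, the gene of F4/80, at 0.33 ± 0.20 (adjusted p = 0.291), and Csf1r, not part of the gates, at -0.09 ± 0.24 (adjusted p = 0.841). Ly6g, at 0.153 ± 0.146 CPM in mMDSC and 5.06 ± 2.98 CPM in gMDSC, missed the filter on counts and was not tested. In vehicle gMDSC 5 it was at 0.438 CPM, against 5.34 to 9.20 CPM in the other 4 vehicle gMDSC libraries. Itgam (CD11b) was higher by 0.84 ± 0.28 (adjusted p = 0.0485), a call that ended when any single library other than vehicle mMDSC 5 or vehicle gMDSC 3 was left out (adjusted p up to 0.109).

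Neutrophil identity genes were higher in gMDSC, with 20 of 23 tested members higher and 1 lower (22 and 1 adjusted over the list alone). For neutrophil identity genes camera gave adjusted p = 5.58e-20, and adjusted p = 0.184 with an estimated correlation. Monocyte identity genes were lower in gMDSC, with 5 of 24 tested members higher and 16 lower (5 and 16 adjusted over the list alone). For monocyte identity genes camera gave adjusted p = 3.23e-05, and adjusted p = 0.209 with an estimated correlation. STAT3 targets were higher, with 15 of 20 tested members higher and 0 lower (16 and 0 adjusted over the list alone). For STAT3 targets camera gave adjusted p = 3.88e-10, and adjusted p = 0.0695 with an estimated correlation. Immediate-early and dissociation stress genes were higher, with 19 of 25 tested members higher and 0 lower (19 and 0 adjusted over the list alone). For immediate-early and dissociation stress genes camera gave adjusted p = 1.59e-09, and adjusted p = 0.187 with an estimated correlation.

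Cell cycle genes were higher in gMDSC, with 17 of 36 tested members higher and 0 lower (19 and 0 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 1.9e-07, and adjusted p = 0.252 with an estimated correlation. NF-kB genes were higher, with 17 of 30 tested members higher and 3 lower (18 and 3 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 4.39e-06, and adjusted p = 0.387 with an estimated correlation. Type I interferon-stimulated genes were higher, with 17 of 30 tested members higher and 3 lower (17 and 3 adjusted over the list alone). For type I interferon-stimulated genes camera gave adjusted p = 0.000634, and adjusted p = 0.456 with an estimated correlation. MHC class II genes were lower, with 1 of 16 tested members higher and 8 lower (1 and 9 adjusted over the list alone). For MHC class II genes camera gave adjusted p = 0.00386, and adjusted p = 0.387 with an estimated correlation. Cholesterol synthesis genes were lower, with 0 of 23 tested members higher and 6 lower (0 and 9 adjusted over the list alone). For cholesterol synthesis genes camera gave adjusted p = 0.000287, and adjusted p = 0.209 with an estimated correlation.

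Suppressive effectors of myeloid cells did not pass, with 8 of 18 members higher and 5 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.138). Hypoxia and glycolysis genes did not pass, with 6 of 30 members higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.425). Interferon-gamma-induced genes did not pass, with 7 of 23 members higher and 7 lower (8 and 9 adjusted over the list alone, camera adjusted p = 0.816). MHC class I presentation did not pass, with 0 of 20 members higher and 3 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.244). MYC and ribosome biogenesis genes did not pass, with 0 of 29 members higher and 1 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.156). Lysosome did not pass, with 6 of 30 members higher and 6 lower (8 and 8 adjusted over the list alone, camera adjusted p = 0.916). Matrix remodelling and angiogenic factors did not pass, with 5 of 24 members higher and 8 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.391).

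Histone acetyltransferases, deacetylases and BET genes did not pass, with 5 of 26 members higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.328). Neutrophil granule proteins did not pass, with 6 of 20 members higher and 6 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.29). Macrophage identity did not pass, with 6 of 25 members higher and 7 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.65). Dendritic cell identity did not pass, with 1 of 18 members higher and 7 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.326). Lymphocyte and NK cell markers did not pass, with 1 of 14 members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.479). Stromal and endothelial markers did not pass, with 2 of 19 members higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.44). Epithelial markers did not pass, with 1 of 7 members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.0646). The medians of the hypoxia list (-0.06) and the lysosome list (-0.05) were negative while the means were 0.18 and 0.13 and the test's direction was up. The count of lower genes was 1521 without vehicle gMDSC 3, when Ptprc also passed (adjusted p = 0.0268).

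CBPi was compared with vehicle in mMDSC to describe what inhibition of these bromodomains changed in the monocytic population. Areg, which encodes the EGF receptor ligand amphiregulin (GeneID 11839, chromosome 5, 91139599 to 91148432), rose from 4.75 ± 3.18 to 118 ± 27.3 CPM (log2 fold change 4.64 ± 0.41 (SE), adjusted p = 3.57e-05). Maged1 (GeneID 94275, chromosome X, 94535474 to 94542025) rose from 37.5 ± 8.1 to 221 ± 43.6 CPM (2.56 ± 0.18, adjusted p = 4.88e-06). The calcium-activated potassium channel gene Kcnn4 (GeneID 16534, chromosome 7, 24369826 to 24385212) fell from 34 ± 10.9 to 2.28 ± 1.89 CPM (-3.88 ± 0.65, adjusted p = 0.0025), and Ccr2, the receptor that draws monocytes to CCL2, from 752 ± 114 to 226 ± 27.1 CPM (-1.73 ± 0.13, adjusted p = 7.84e-06). The urokinase gene Plau fell from 349 ± 42.2 to 65.4 ± 12.9 CPM (-2.42 ± 0.15, adjusted p = 3.01e-06).

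Of 11912 genes tested, 360 rose and 660 fell, and 2664 had an unadjusted p under 0.05. The groups did not overlap for 1161 genes (9.75%, chance 0.794%). Other genes with the largest rises were Iqcn (3.41 ± 0.58, adjusted p = 0.00275), Trp53i11 (3.15 ± 0.36, adjusted p = 0.000202), Cep170b (2.28 ± 0.63, adjusted p = 0.0412), the gelatinase gene Mmp9 (2.27 ± 0.34, adjusted p = 0.00133), and GeneID:19368 with Raet1e, an NKG2D ligand gene (2.18 ± 0.28, adjusted p = 0.000489), which had identical counts and could not be separated. The largest falls also included coagulation factor VII, F7 (-4.27 ± 0.87, adjusted p = 0.00863), the sulfotransferase Chst1 (-3.37 ± 0.70, adjusted p = 0.00966), Lhfpl2 (-3.33 ± 0.51, adjusted p = 0.0014), the keratin Krt80 (-3.06 ± 0.40, adjusted p = 0.000504), Fcrl5 (-3.04 ± 0.32, adjusted p = 9.85e-05), the metalloprotease Adam19 (-2.97 ± 0.39, adjusted p = 0.000489) and the toll-like receptor Tlr12 (-2.87 ± 0.31, adjusted p = 0.000135). The groups of all these genes except Cep170b did not overlap. The Cep170b call ended without vehicle 2, 3 or 4 or CBPi 6, 7 or 10 (adjusted p up to 0.115).

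The genes of the drug's targets, Crebbp (0.20 ± 0.21, adjusted p = 0.633) and Ep300 (0.16 ± 0.16, adjusted p = 0.607), did not pass the test, nor did Arg1 (0.82 ± 0.50, adjusted p = 0.368), Nos2 (0.53 ± 0.53, adjusted p = 0.61), Myc (-0.44 ± 0.15, adjusted p = 0.103), Stat3 (-0.06 ± 0.11, adjusted p = 0.805), S100a8 (-0.15 ± 0.39, adjusted p = 0.867), S100a9 (-0.29 ± 0.48, adjusted p = 0.785), Il1b (0.21 ± 0.22, adjusted p = 0.619) or Tnf (0.46 ± 0.17, adjusted p = 0.133). Tnf passed without vehicle 4 (adjusted p = 0.0127) and with limma (0.00649). The cytokine gene Il6 rose from 85.4 ± 36.3 to 218 ± 41.7 CPM (1.36 ± 0.25, adjusted p = 0.00533). Cd274, which encodes PD-L1, fell by 0.68 (adjusted p = 0.0486), a call that ended when any library other than vehicle 3 was left out (adjusted p up to 0.115).

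MHC class II genes fell in mMDSC, with 0 of 16 tested members higher and 10 lower (1 and 10 adjusted over the list alone). For MHC class II genes camera gave adjusted p = 1.54e-06, and adjusted p = 0.217 with an estimated correlation. H2-Ab1, a chain of the class II molecule, went from 7482 ± 1639 to 2527 ± 779 CPM (-1.57 ± 0.21, adjusted p = 0.000569), its chaperone Cd74 changed by -1.39 ± 0.24 (adjusted p = 0.00333) and the class II transactivator gene Ciita by -2.29 ± 0.24 (adjusted p = 9.29e-05). Immediate-early and dissociation stress genes rose, with 10 of 26 tested members higher and 0 lower (12 and 0 adjusted over the list alone). For immediate-early and dissociation stress genes camera gave adjusted p = 1.99e-08, and adjusted p = 0.141 with an estimated correlation. They included Egr3 4.23, Egr1 1.55, Fosb 1.06 and Jun 0.98. Egr3 did not reach the mean of 10 CPM required of the largest rises named above. Type I interferon-stimulated genes rose, with 10 of 30 tested members higher and 0 lower (17 and 0 adjusted over the list alone). For type I interferon-stimulated genes camera gave adjusted p = 1.54e-06, and adjusted p = 0.217 with an estimated correlation. They included Mx2 0.84, Usp18 0.64 and Oasl2 0.57.

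Hypoxia and glycolysis genes rose in mMDSC, with 7 of 31 tested members higher and 0 lower (15 and 1 adjusted over the list alone). For hypoxia and glycolysis genes camera gave adjusted p = 5.85e-05, and adjusted p = 0.217 with an estimated correlation. They included Egln3 1.25, Vegfa 1.15 and Ndrg1 0.84. NF-kB genes rose, with 8 of 30 tested members higher and 1 lower (8 and 1 adjusted over the list alone). For NF-kB genes camera gave adjusted p = 0.00421, and adjusted p = 0.434 with an estimated correlation. They included Cxcl3 1.73, Cxcl1 1.40 and Traf1 -1.05. Histone acetyltransferase, deacetylase and BET genes rose, with 1 of 26 tested members higher and 0 lower (1 and 0 adjusted over the list alone). For histone acetyltransferase, deacetylase and BET genes camera gave adjusted p = 0.0304, and adjusted p = 0.217 with an estimated correlation. The member of this list that rose was the BET gene Brd2 (0.47). Without vehicle 2 or vehicle 4 that list was not past the test (adjusted p up to 0.0753).

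Lysosome genes fell in mMDSC, with 1 of 29 tested members higher and 10 lower (2 and 15 adjusted over the list alone). For lysosome genes camera gave adjusted p = 0.000121, and adjusted p = 0.113 with an estimated correlation. Ctsh of this list fell (-0.76). Cell cycle genes fell, with 0 of 36 tested members higher and 6 lower (0 and 7 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 1.42e-05, and adjusted p = 0.217 with an estimated correlation. They included Birc5 -1.59, Rrm2 -1.41 and Mki67 -1.16. Monocyte identity genes fell, with 2 of 24 tested members higher and 7 lower (2 and 8 adjusted over the list alone). For monocyte identity genes camera gave adjusted p = 0.00783, and adjusted p = 0.3 with an estimated correlation. They included Treml4 -1.72 and Ly6c2 -1.24. Macrophage identity genes fell, with 2 of 25 tested members higher and 7 lower (3 and 10 adjusted over the list alone). For macrophage identity genes camera gave adjusted p = 0.00515, and adjusted p = 0.217 with an estimated correlation. They included Gpnmb -2.67 and Ms4a7 -1.35. Mrc1 of the macrophage list rose (0.72).

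Lymphocyte and NK cell markers fell in mMDSC, with 0 of 13 tested members higher and 1 lower (0 and 2 adjusted over the list alone). For lymphocyte and NK cell markers camera gave adjusted p = 0.00595, and adjusted p = 0.217 with an estimated correlation. Epithelial markers fell, with 0 of 6 tested members higher and 2 lower (0 and 2 adjusted over the list alone). For epithelial markers camera gave adjusted p = 0.00421, and adjusted p = 0.141 with an estimated correlation. The mean log2 CPM of the lymphocyte and NK list was low in mMDSC, at 1.18 with vehicle and 0.149 with CBPi. That of the epithelial list was 0.161 and -0.7, so both falls were in lists of low level. The epithelial calls, Krt7 and Krt8, and the lymphocyte and NK call, Klrb1c, ended without the libraries numbered 3 and 7 (adjusted p = 0.108, 0.147 and 0.0921). They also ended with the neutrophil identity score as a covariate (0.163, 0.236 and 0.208). Neutrophil granule genes fell, with 1 of 20 tested members higher and 6 lower (1 and 7 adjusted over the list alone). For neutrophil granule genes camera gave adjusted p = 0.0146, and adjusted p = 0.3 with an estimated correlation. In the granule list Mmp9 rose. This list was not past the test without vehicle 3 or CBPi 8 (adjusted p up to 0.0566).

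Suppressive effectors of myeloid cells did not pass, with 2 of 20 members higher and 5 lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.201). STAT3 target genes did not pass, with 4 of 21 members higher and 3 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.747). Interferon-gamma-induced genes did not pass, with 1 of 23 members higher and 6 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.282). MHC class I presentation did not pass, with 0 of 20 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.406). MYC and ribosome biogenesis genes did not pass, with 1 of 29 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.753). Cholesterol synthesis did not pass, with 0 of 23 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.37). Matrix remodelling and angiogenic factors did not pass, with 8 of 25 members higher and 3 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.112).

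Neutrophil identity did not pass, with 3 of 22 members higher and 4 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.09). Dendritic cell identity did not pass, with 1 of 21 members higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.959). Stromal and endothelial markers did not pass, with 0 of 19 members higher and 2 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.09). The STAT3 list had a median of -0.02 and a mean of 0.10, with the test's direction up. Of the lists with too few tested members, the platelet gene Pf4 rose (1.84 ± 0.31, adjusted p = 0.00261) among erythroid and platelet markers, and Ear2, an eosinophil ribonuclease gene of a close family at 1.43 ± 0.916 CPM, fell (-4.15 ± 0.73, adjusted p = 0.00359). The neutrophil identity list passed without vehicle 1 (adjusted p = 0.0351), and the stromal list without vehicle 1, vehicle 2 or CBPi 6 (down to 0.0413).

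The number of changed genes in mMDSC was 534 without the libraries numbered 3 and 7, 571 with the neutrophil identity score as a covariate, 639 with all 20 libraries in the fit, 1647 with DESeq2 and 1688 with limma. The count of genes that rose was 221 without vehicle 2, 235 without vehicle 3, 231 without CBPi 9 and 226 without CBPi 10. With that covariate the calls of Cd74 (adjusted p = 0.0509), Birc5 (0.0588), Brd2 (0.0738), Ear2 (0.0552) and Cep170b (0.151) ended. Without libraries 3 and 7 those of Chst1 (0.0631), Birc5 (0.0597), Brd2 (0.0637) and Cep170b (0.213) ended, as did those of the acetyltransferase and granule lists (0.0577 and 0.0975). With all 20 libraries in the fit those of Ear2 (0.0611), Oasl2 (0.0516), Cd274 (0.231) and Cep170b (0.0953) ended, DESeq2 gave Ear2 no adjusted p, and with limma Cep170b was at 0.073.

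**Figure D2:**
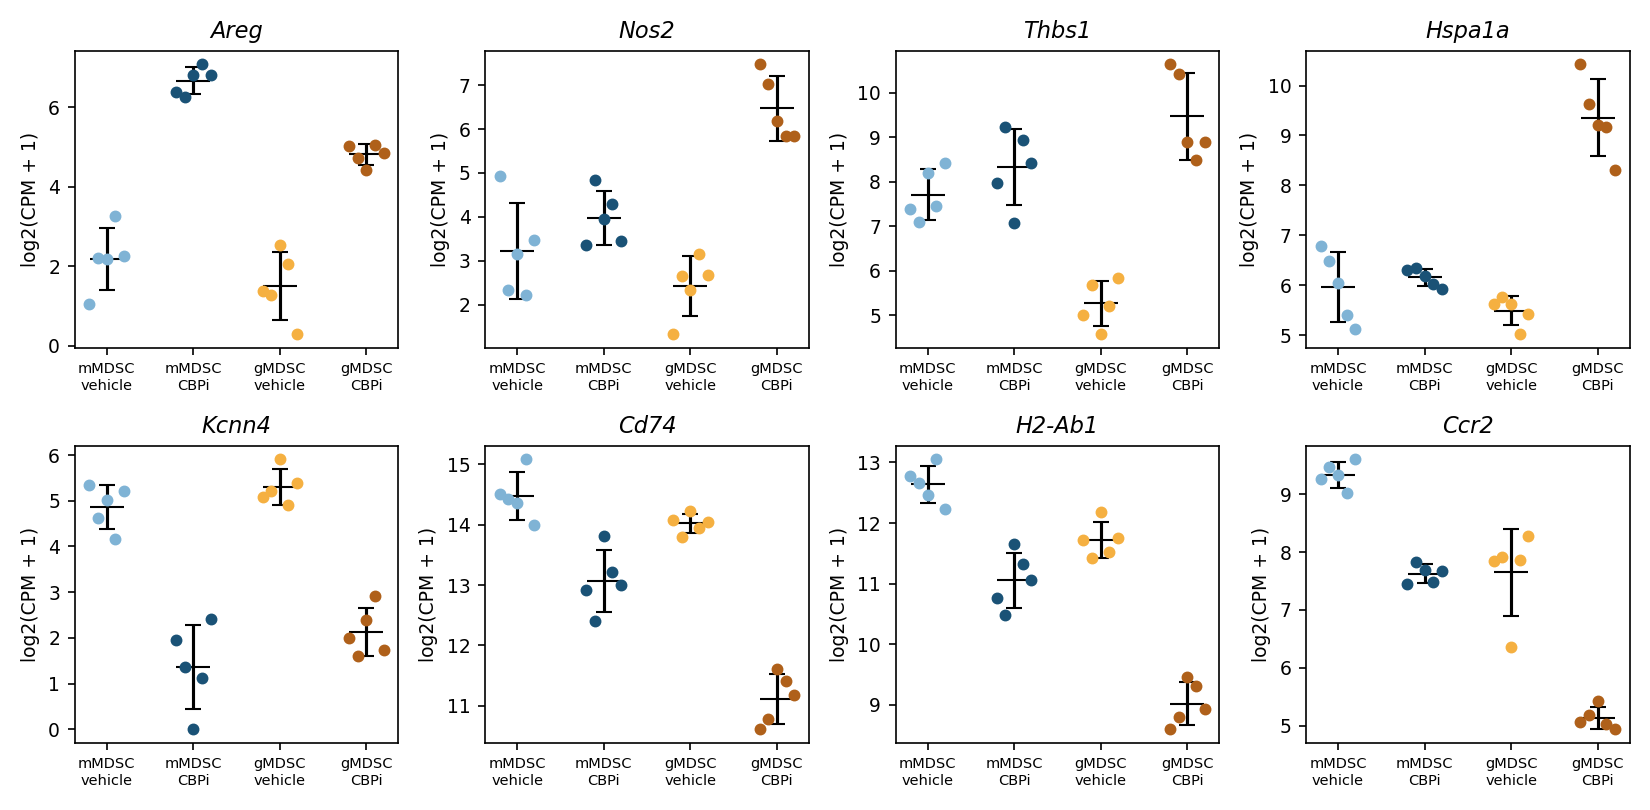
Levels of 8 genes as log2(CPM + 1), 1 point per library in the 4 groups, with the mean and SD of each group. Areg lay higher with CBPi in both cell types and Cd74, H2-Ab1, Ccr2 and Kcnn4 lower, while Nos2, Thbs1 and Hspa1a passed the test only in gMDSC.

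CBPi was compared with vehicle in gMDSC by the same test. Thbs1, the gene of the matrix glycoprotein thrombospondin-1 (GeneID 21825, chromosome 2, 118111876 to 118127133), rose from 34 ± 12.6 to 754 ± 508 CPM (log2 fold change 4.47 ± 0.47 (SE), adjusted p = 0.000134). Nos2, the inducible nitric oxide synthase (GeneID 18126, chromosome 11, 78920787 to 78960226), rose from 4.14 ± 2 to 86.5 ± 46.5 CPM (4.37 ± 0.46, adjusted p = 0.000116). The heat-shock chaperone genes Hspa1a (GeneID 193740, chromosome 17, 34969359 to 34972156) and Hspa1b, near-identical copies between which reads may be shared, rose by 4.07 ± 0.35 (adjusted p = 2.23e-05) and 4.03 ± 0.34 (adjusted p = 2.13e-05). Krt18, a keratin gene (GeneID 16668, chromosome 15, 102028216 to 102032026), fell from 29.2 ± 9.88 to 1.35 ± 1.3 CPM (-4.44 ± 0.57, adjusted p = 0.000542), and the chitinase-like Chil1 from 316 ± 87.4 to 25.2 ± 10.3 CPM (-3.65 ± 0.32, adjusted p = 2.27e-05).

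Of 11694 genes tested, 489 rose and 646 fell, and 3030 had an unadjusted p under 0.05. The groups did not overlap for 1416 genes (12.1%, chance 0.794%), among them every gene of this paragraph. Further large rises were those of Areg (3.69 ± 0.56, adjusted p = 0.0018), the lipid droplet gene Hilpda (3.66 ± 0.53, adjusted p = 0.00126), the versican gene Vcan (3.51 ± 0.78, adjusted p = 0.0144) and Ero1a, an oxidase of the endoplasmic reticulum (3.50 ± 0.36, adjusted p = 0.000104). Further large falls were those of the sialic acid hydroxylase gene Cmah (-4.27 ± 0.52, adjusted p = 0.000386), the potassium channel Kcnj8 (-4.09 ± 0.74, adjusted p = 0.00494), the calpain Capn3 (-4.02 ± 0.55, adjusted p = 0.000881), Amer2 (-3.90 ± 0.25, adjusted p = 4.1e-06), the oxysterol receptor Gpr183 (-3.55 ± 0.36, adjusted p = 9.37e-05) and Kcnn4 (-3.42 ± 0.35, adjusted p = 0.000112). The Vcan call ended without CBPi 6 and 7 together (adjusted p = 0.123).

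Crebbp (-0.04 ± 0.24, adjusted p = 0.945), Ep300 (0.29 ± 0.17, adjusted p = 0.322), Arg1 (0.22 ± 0.64, adjusted p = 0.869), Cd274 (0.10 ± 0.31, adjusted p = 0.875), Myc (-0.10 ± 0.23, adjusted p = 0.821), Stat3 (0.31 ± 0.21, adjusted p = 0.373), Il1b (-0.08 ± 0.23, adjusted p = 0.874), Tnf (0.55 ± 0.22, adjusted p = 0.133), S100a8 (-1.10 ± 0.43, adjusted p = 0.123) and S100a9 (-1.38 ± 0.45, adjusted p = 0.0719) did not pass the test in gMDSC. S100a9 passed without vehicle 5 (adjusted p = 0.0349) and with limma (0.0442). Il6 rose from 3.41 ± 2.33 to 13.7 ± 4.16 CPM (2.02 ± 0.49, adjusted p = 0.0212), a call that ended without vehicle 1, CBPi 7 or CBPi 8 (adjusted p up to 0.0578).

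Hypoxia and glycolysis genes rose in gMDSC, with 23 of 31 tested members higher and 0 lower (27 and 1 adjusted over the list alone). For hypoxia and glycolysis genes camera gave adjusted p = 2.77e-17, and adjusted p = 0.23 with an estimated correlation. They included Aldoc 4.68, Adm 4.34, Vegfa 2.89 and Bnip3 2.70. The mean log2 CPM of the list was 6.05 to 7.17 with CBPi, and 4.69 to 5.04 with vehicle. MHC class II genes fell in gMDSC, with 0 of 16 tested members higher and 9 lower (0 and 9 adjusted over the list alone). For MHC class II genes camera gave adjusted p = 6.85e-09, and adjusted p = 0.23 with an estimated correlation. Cd74 went from 14342 ± 1434 to 2024 ± 576 CPM (-2.83 ± 0.21, adjusted p = 9.18e-06), and H2-Aa, H2-Ab1 and Ciita changed by -2.99 ± 0.22 (adjusted p = 8.18e-06), -2.65 ± 0.21 (adjusted p = 1.39e-05) and -3.21 ± 0.32 (adjusted p = 9.37e-05). Immediate-early and dissociation stress genes rose in gMDSC, with 13 of 26 tested members higher and 0 lower (16 and 0 adjusted over the list alone). For immediate-early and dissociation stress genes camera gave adjusted p = 6.85e-09, and adjusted p = 0.388 with an estimated correlation. They included Hsp90aa1 2.16, Hspa8 1.88 and Jun 1.63. Type I interferon-stimulated genes rose, with 11 of 30 tested members higher and 0 lower (15 and 1 adjusted over the list alone). For type I interferon-stimulated genes camera gave adjusted p = 3.55e-05, and adjusted p = 0.509 with an estimated correlation. They included Mx2 2.89 and Ifit2 1.52.

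Cell cycle genes fell in gMDSC, with 0 of 36 tested members higher and 5 lower (0 and 13 adjusted over the list alone). For cell cycle genes camera gave adjusted p = 7.16e-08, and adjusted p = 0.23 with an estimated correlation. They included Birc5 -1.31 and Mki67 -1.26. Neutrophil granule genes fell, with 0 of 17 tested members higher and 7 lower (0 and 7 adjusted over the list alone). For neutrophil granule genes camera gave adjusted p = 0.0373, and adjusted p = 0.509 with an estimated correlation. They included Ngp -2.64, Camp -2.46, Ltf -1.61 and Lyz2 -0.91. MYC and ribosome biogenesis genes fell, with 1 of 29 tested members higher and 2 lower (1 and 2 adjusted over the list alone). For MYC and ribosome biogenesis genes camera gave adjusted p = 0.0467, and adjusted p = 0.509 with an estimated correlation. Lymphocyte and NK cell markers fell, with 0 of 13 tested members higher and 2 lower (0 and 2 adjusted over the list alone). For lymphocyte and NK cell markers camera gave adjusted p = 0.0374, and adjusted p = 0.461 with an estimated correlation. Epithelial markers fell, with 0 of 7 tested members higher and 2 lower (0 and 4 adjusted over the list alone). For epithelial markers camera gave adjusted p = 0.0191, and adjusted p = 0.23 with an estimated correlation. The mean log2 CPM of the lymphocyte and NK list was low in gMDSC too, at 0.583 with vehicle and -0.113 with CBPi. That of the epithelial list was 1.39 and 0.0204.

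Suppressive effectors of myeloid cells did not pass, with 3 of 18 members higher and 4 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.948). STAT3 target genes did not pass, with 1 of 20 members higher and 2 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.948). Interferon-gamma-induced genes did not pass, with 1 of 23 members higher and 4 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.494). MHC class I presentation did not pass, with 0 of 20 members higher and 2 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.0648). NF-kB inflammatory cytokines and feedback genes did not pass, with 8 of 30 members higher and 4 lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.204). Cholesterol synthesis did not pass, with 0 of 23 members higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.204). Lysosome did not pass, with 4 of 30 members higher and 5 lower (6 and 10 adjusted over the list alone, camera adjusted p = 0.0907).

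Matrix remodelling and angiogenic factors did not pass, with 5 of 25 members higher and 3 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.0724). Histone acetyltransferases, deacetylases and BET genes did not pass, with 1 of 26 members higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.13). Neutrophil identity did not pass, with 0 of 24 members higher and 4 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.0724). Monocyte identity did not pass, with 3 of 24 members higher and 8 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.271). Macrophage identity did not pass, with 1 of 23 members higher and 3 lower (5 and 8 adjusted over the list alone, camera adjusted p = 0.0733). Dendritic cell identity did not pass, with 1 of 16 members higher and 2 lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.948). Stromal and endothelial markers did not pass, with 0 of 18 members higher and 2 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.72). The medians of the STAT3 list (0.13) and the dendritic cell list (0.45) were positive while the test's direction was down. Ly6g, the gene of the gMDSC gate, went from 4.44 ± 2.58 to 0.857 ± 0.584 CPM and did not pass (-2.37 ± 0.70, adjusted p = 0.0502). The monocyte marker Ccr2 fell (-2.64 ± 0.29, adjusted p = 0.000195) and F13a1 rose (3.36 ± 0.52, adjusted p = 0.00203). The eosinophil markers Siglecf (-1.97 ± 0.20, adjusted p = 9.37e-05) and Ccr3 (-2.40 ± 0.44, adjusted p = 0.0056), of a list with too few tested members, fell.

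Left-out libraries ended the calls of these gMDSC lists: epithelial without vehicle 1 (adjusted p = 0.0558), lymphocyte and NK without vehicle 1, vehicle 4, CBPi 6 or CBPi 7 (up to 0.112), MYC and ribosome without vehicle 1, 3 or 5 or CBPi 6, 7 or 8 (up to 0.110), and granule without vehicle 1, 3 or 4 or CBPi 9 (up to 0.0702). Without CBPi 6 the gMDSC count of changed genes was 708, without CBPi 7 it was 587 and without both 306, and the count of falls was 410 without CBPi 8 or without CBPi 10. DESeq2 gave 1926 changed genes and a fit of all 20 libraries 2182, in which the calls of Ltf (adjusted p = 0.342) and Ccr3 (0.0676) ended. Without CBPi 6 and 7 together the calls of Il6 (0.122), Birc5 (0.0517) and the MYC and lymphocyte lists (0.199 and 0.269) ended, and without libraries 3 and 7 those of the MYC, lymphocyte and granule lists (0.161, 0.122 and 0.0625).

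Of the lists not past the test in gMDSC, neutrophil identity passed without vehicle 2, vehicle 5, CBPi 6 or CBPi 7 (adjusted p down to 0.00195) or CBPi 6 and 7 together (0.000586), in each case lower. Macrophage identity, also lower, passed without vehicle 4 or CBPi 9 (down to 0.0472). MHC class I genes passed without vehicle 2, vehicle 5 or CBPi 8 (down to 0.0257), and the matrix list without vehicle 4 (0.0472).

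**Figure D3:**
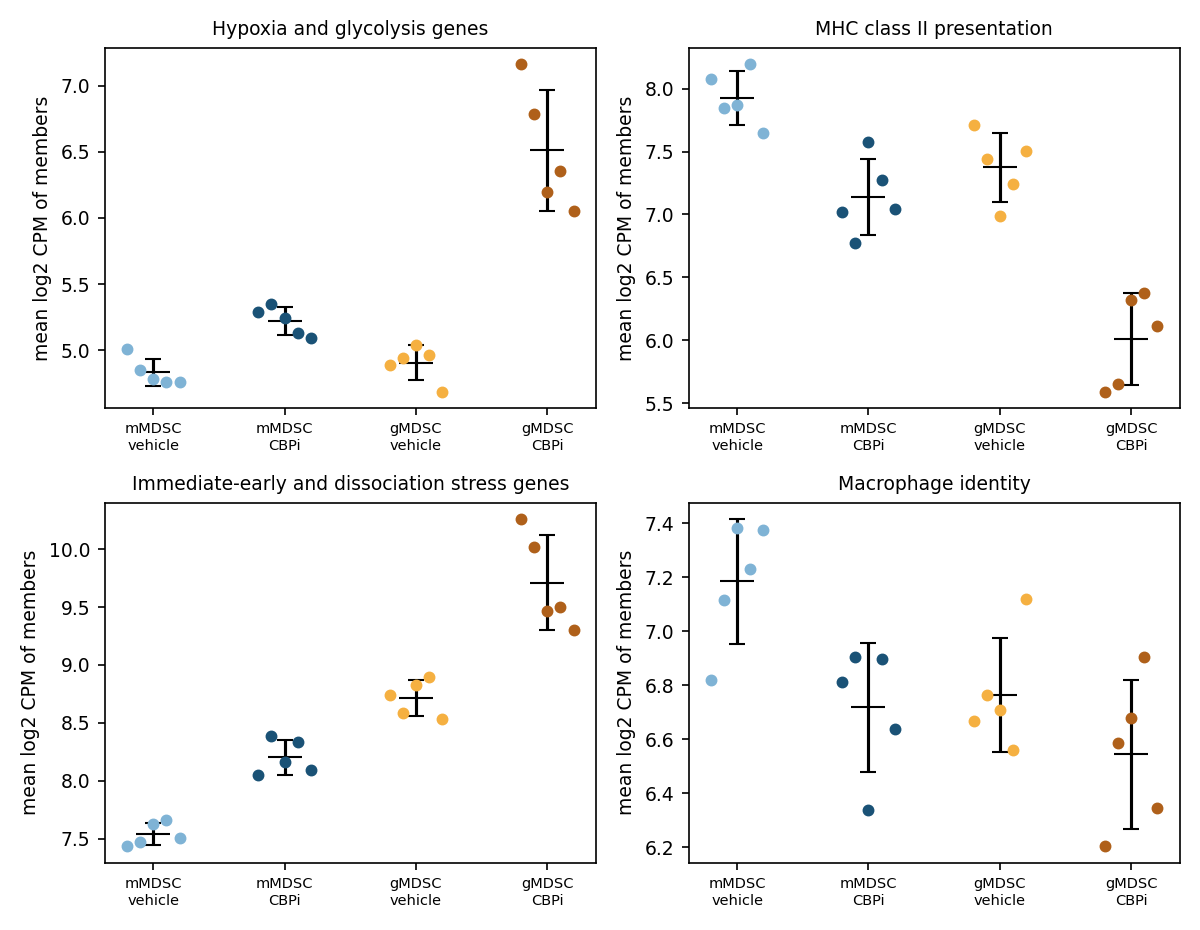
Mean log2 CPM of the members of 4 gene lists, 1 point per library in the 4 groups, with the mean and SD of each group. Hypoxia and glycolysis genes in gMDSC lay at 6.05 to 7.17 with CBPi and 4.69 to 5.04 with vehicle, and MHC class II genes at 5.59 to 6.37 and 6.99 to 7.71.

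The difference between the responses of gMDSC and mMDSC to CBPi was tested as an interaction over all 20 libraries. Hspa1a was at 67.4 ± 31.5 CPM and 70.8 ± 8.63 CPM in mMDSC with vehicle and CBPi, and at 44.6 ± 8.44 CPM and 731 ± 398 CPM in gMDSC (difference of log2 fold changes 3.96 ± 0.46 (adjusted p = 0.00026)). Thbs1 (3.73 ± 0.61, adjusted p = 0.00384), Hspa1b (3.94 ± 0.49, adjusted p = 0.000398), Nos2 (3.81 ± 0.73, adjusted p = 0.0175) and Fry (3.99 ± 0.92, adjusted p = 0.0442) also responded more in gMDSC. The lectin receptor gene Clec4n (GeneID 56620, chromosome 6, 123229843 to 123247024) was at 224 ± 41.2 CPM and 282 ± 78.2 CPM in mMDSC and at 1098 ± 352 CPM and 299 ± 44 CPM in gMDSC (-2.21 ± 0.30, adjusted p = 0.00148). Oscp1 (-6.47 ± 0.98, adjusted p = 0.00307), the transcription factor Egr3 (-3.55 ± 0.77, adjusted p = 0.0344), Galnt12 (-2.24 ± 0.48, adjusted p = 0.0344), Lrg1 (-2.15 ± 0.40, adjusted p = 0.0148) and Cd74 (-1.49 ± 0.33, adjusted p = 0.0355) had lower log2 fold changes in gMDSC than in mMDSC.

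Of 12688 genes, 63 had a higher and 29 a lower log2 fold change in gMDSC, and 1454 had an unadjusted p under 0.05. Crebbp (-0.29), Ep300 (0.07), Arg1 (-0.63), Cd274 (0.72), Myc (0.29), Stat3 (0.32), S100a8 (-1.01), S100a9 (-1.15), Il1b (-0.35), Tnf (0.04), Il6 (0.63) and H2-Ab1 (-1.14, adjusted p = 0.0871) did not pass the test of the difference. H2-Ab1 passed with DESeq2 (adjusted p = 0.0205).

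Hypoxia and glycolysis genes rose more in gMDSC, with 11 of 31 tested members higher and 0 lower (19 and 0 adjusted over the list alone). For hypoxia and glycolysis genes camera gave adjusted p = 7.76e-22, and adjusted p = 0.107 with an estimated correlation. They included Aldoc 3.66, Ero1a 2.81, Pfkfb3 2.37 and Bnip3 2.29. MHC class II genes fell more in gMDSC, with 0 of 16 tested members higher and 3 lower (0 and 6 adjusted over the list alone). For MHC class II genes camera gave adjusted p = 5.73e-05, and adjusted p = 0.869 with an estimated correlation. They included H2-Aa -1.52 and H2-Eb1 -1.54. MYC and ribosome biogenesis genes had lower changes in gMDSC, with 0 of 29 tested members higher and 0 lower (0 and 0 adjusted over the list alone). For MYC and ribosome biogenesis genes camera gave adjusted p = 0.0378, and adjusted p = 0.869 with an estimated correlation.

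Suppressive effectors of myeloid cells did not pass, with 2 of 21 members higher and 0 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.418). STAT3 target genes did not pass, with 1 of 21 members higher and 1 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.764). Type I interferon-stimulated genes did not pass, with 1 of 30 members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.257). Interferon-gamma-induced genes did not pass, with 1 of 23 members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.93). MHC class I presentation did not pass, with 0 of 20 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.133). NF-kB inflammatory cytokines and feedback genes did not pass, with 0 of 30 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.438). Immediate-early and dissociation stress genes did not pass, with 4 of 26 members higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.183).

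Cell cycle did not pass, with 0 of 36 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.922). Cholesterol synthesis did not pass, with 0 of 24 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.133). Lysosome did not pass, with 1 of 30 members higher and 0 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.555). Matrix remodelling and angiogenic factors did not pass, with 3 of 25 members higher and 1 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.29). Histone acetyltransferases, deacetylases and BET genes did not pass, with 0 of 26 members higher and 0 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.93). Neutrophil granule proteins did not pass, with 0 of 21 members higher and 1 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.764). Neutrophil identity did not pass, with 0 of 24 members higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.93).

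Monocyte identity did not pass, with 1 of 24 members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.764). Macrophage identity did not pass, with 2 of 25 members higher and 0 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.93). Dendritic cell identity did not pass, with 0 of 23 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.713). Lymphocyte and NK cell markers did not pass, with 0 of 15 members higher and 0 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.93). Stromal and endothelial markers did not pass, with 0 of 21 members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.62). Epithelial markers did not pass, with 0 of 8 members higher and 0 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.4). Erythroid and platelet markers did not pass, with 0 of 8 members higher and 0 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.318). The median, mean and test direction differed in sign for STAT3 targets (-0.07, 0.14, down), interferon-gamma-induced genes (-0.11, 0.05, down), acetyltransferase and BET genes (-0.05, -0.04, up) and monocyte identity (-0.03, 0.24, up).

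Single libraries decided several of these differences. The count of 92 genes was 58 without vehicle mMDSC 5, 53 without CBPi mMDSC 10, 47 without vehicle gMDSC 4, 57 without CBPi gMDSC 6, 34 without CBPi gMDSC 7 and 36 without CBPi gMDSC 6 and 7 together, and was 40 without the libraries numbered 3 and 7 and 277 with DESeq2. The count of lower changes, 29, was 12, 12, 11 and 11 without vehicle mMDSC 1, 2, 3 and 5, 15, 14, 13 and 10 without CBPi mMDSC 6, 8, 9 and 10, 16 and 11 without vehicle gMDSC 1 and 4, and 19, 11 and 16 without CBPi gMDSC 6, 7 and 8, and the count of higher changes, 63, was 36, 38 and 23 without vehicle gMDSC 4, CBPi gMDSC 6 and CBPi gMDSC 7. Calls ended in 13 of the 20 fits with 1 library left out for Fry, 13 of the 20 for Cd74, 11 of the 20 for Egr3 and 10 of the 20 for Galnt12 (adjusted p up to 0.0985, 0.0898, 0.0724 and 0.0768), in each case including the omission of vehicle gMDSC 4, CBPi gMDSC 6 and CBPi gMDSC 7. The Nos2 difference did not pass without CBPi gMDSC 6 and 7 together (adjusted p = 0.0982) or with limma (0.0681), nor without libraries 3 and 7 (0.0525). With the replicate number as a block 52 genes passed. There the MYC and ribosome list (adjusted p = 0.103) and the differences of Nos2 (0.125) and Egr3 (0.087) did not pass. Without libraries 3 and 7 those of Cd74 (0.0993), Fry (0.138) and Galnt12 (0.133) did not pass, and without CBPi gMDSC 6 and 7 those of Cd74 (0.158), Egr3 (0.0861), Fry (0.238) and Galnt12 (0.158). With limma Fry was at 0.307. The interferon list passed for the difference without vehicle mMDSC 1, vehicle gMDSC 1 or CBPi gMDSC 9 (adjusted p down to 0.0151), the immediate-early list without vehicle mMDSC 1 or CBPi gMDSC 10 (down to 0.0254), and MHC class I genes without vehicle gMDSC 2 (0.0364). The MYC and ribosome list lost its call in 14 of the 20 such fits (up to 0.184), and the number of lists past the test was 5 without vehicle mMDSC 1.

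The responses of the 2 cell types were then set against each other, over 11353 genes tested in both comparisons, which share no library. They share mice if same-numbered libraries of the 2 cell types came from one mouse. The counts given by chance below assume independent comparisons. Genes that rose in both numbered 96, where 14.8 would be shared by chance, and included Areg, Maged1, Trp53i11, Iqcn, the sodium pump subunit gene Atp1b3 (2.10 in mMDSC and 2.55 in gMDSC), the chemokine Cxcl3 (1.73 and 3.48), the glucocorticoid-responsive Fkbp5 (1.84 and 1.12) and the histone demethylase Kdm5b (1.44 and 1.27). Genes that fell in both numbered 281, where chance gives 35.5, and included Kcnn4, Ccr2, Plau, Ciita, Cd74, Gpr183 (-2.69 and -3.55), Gpr34 (-2.81 and -2.88), the phosphatase gene Acp5 (-2.72 and -1.83) and Tmem119 (-2.52 and -1.72). Opposite calls numbered 3, where chance gives 46.5. Of 1719 genes called in either comparison, 88.8% had the same sign in both. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.511 and Spearman's rho 0.516. The shared count of 377 was 251 without CBPi gMDSC 7, 156 without CBPi gMDSC 6 and 7 together, 220 without the libraries numbered 3 and 7, 629 with DESeq2 and 671 with limma. Genes named here outside the rule for named genes were chosen after their values were seen.

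**Figure D4:**
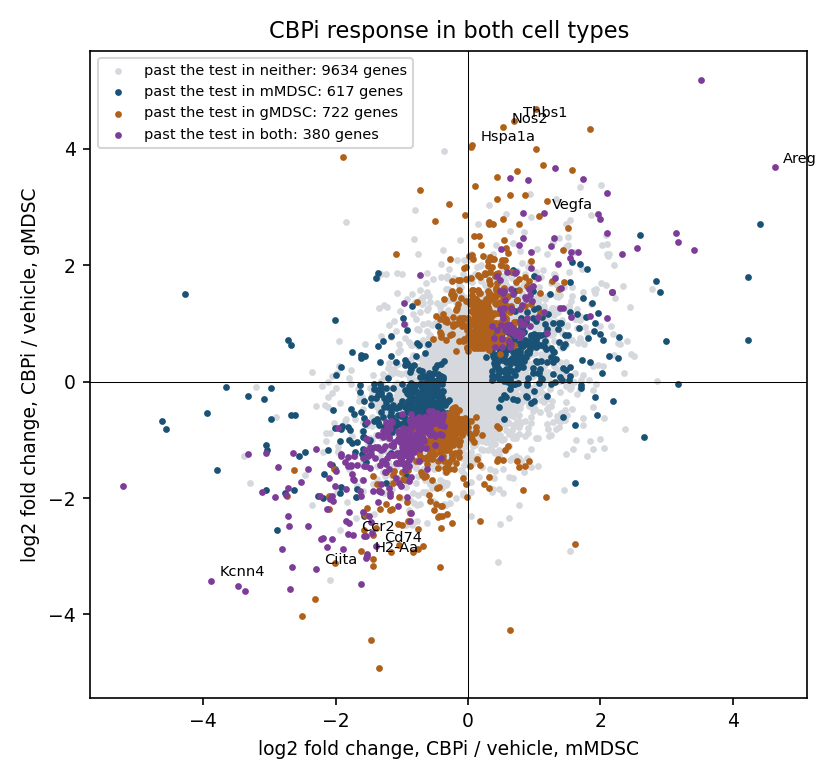
Log2 fold change with CBPi in gMDSC (y axis) against mMDSC (x axis), 1 point per gene tested in both comparisons, coloured by the comparison in which it passed the test. Of 11353 genes, 380 passed in both, 617 in mMDSC alone, 722 in gMDSC alone and 9634 in neither.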

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

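The tests of left-out libraries 6 and 7, of thinned counts, of immediate-early genes, of marker lists against MHC class II, and all counts over splits of the libraries were chosen only after the results were seen; the test of carried-over mMDSC RNA was not.

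Hypoxia and glycolysis genes rose more with CBPi in gMDSC than in mMDSC, with a difference of the list's mean log2 CPM change of 1.22 (SE 0.224) and a median difference over genes of 1.20. Without CBPi gMDSC 6 and 7, the libraries highest in this list, the difference was 0.907 (SE 0.125), and with all libraries thinned to the smallest total the median was 1.18, which argues against those libraries or depth as the whole cause. Immediate-early genes without the heat-shock members differed by -0.19 (SE 0.230), which argues against the part of a digestion and sorting response that they measure. The whole list, as fixed beforehand with those members, differed by a median of 0.042 and a mean of 0.34 over genes. What stays open includes lower oxygen or a changed tumour in treated mice, a stress response carried by heat-shock genes, and a direct response of the granulocytic cells. The mix of cells sorted as gMDSC and the tumour line of each library, which the labels do not give, stay open as well. None of these was tested here. In 100 splits of the libraries the real one gave the list its smallest p for the difference. Those splits mixed vehicle and CBPi within each cell type, so they do not test whether the responses differ. At least as many lists as the real 3 were called in 66 of 100 splits (highest other 13), so chance is not excluded for the number of lists.

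MHC class II genes fell with CBPi in gMDSC, by 1.37 in mean log2 CPM (SE 0.205, exact permutation p = 0.00794, the smallest this design gives), and the median of the difference from mMDSC was -0.62. The macrophage list changed by -0.22 (SE 0.156) and the monocyte list by 0.0897 (SE 0.129), each less than the MHC class II list (exact permutation p = 0.00794). Members of both lists went both ways, such as Apoe (-1.15) and Hmox1 (1.85), and Ccr2 (-2.64) and Vcan (3.51), so these means do not settle a loss of either cell type. Apoe, Trem2 (-1.09) and C1qc (-0.67, adjusted p = 0.0651) changed less than Cd74 (-2.83), but a loss of macrophages or monocytes stays open, and the macrophage list passed as lower without vehicle 4 or CBPi 9 (adjusted p down to 0.0472). The dendritic cell list changed by 0.34 (SE 0.301), but its median of 2.13 CPM in vehicle gMDSC lies too low to decide, so fewer dendritic cells cannot be told apart from a change within the gMDSC, and in which cells the genes fell stays open.

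CBPi changed 377 genes in the same direction in both cell types. If mMDSC or their RNA had been carried into the gMDSC sort, the shared genes would lie near the level of carried-over monocyte genes, but 0.532% of 376 lay at or under 5% of their vehicle mMDSC level in vehicle gMDSC, and their median was 114.5%. Shared genes had to pass the filter on counts in gMDSC, which can remove genes at so low a level. These levels cover vehicle libraries alone. The monocyte genes F13a1 and Vcan rose in gMDSC with CBPi, so carry-over into the treated libraries was not tested. With libraries thinned to the smallest total 380 genes were shared, which argues against depth. A macrophage-like cell sorted into both gates stays open and was not tested. Other splits of the libraries called at most 1 gene in mMDSC and 2 in gMDSC. Their shared count (highest other 0) was therefore bound to lie near 0, so the 100 splits do not test the sharing. Mice shared by the 2 comparisons, which the labels neither state nor exclude, stay open as well.

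Splits of the libraries, 100 for each comparison with the real one included, argued against chance for 3 counts of genes, each reached by 1 split. These were 1020 in mMDSC (highest other 1), 1135 in gMDSC (highest other 2) and 2514 between cell types (highest other 0). The 92 for the difference (highest other 1) were also reached by 1 split. Splits for the difference mixed vehicle and CBPi within each cell type, which moves changes shared by both into the spread. They therefore do not test whether the responses differ. For lists, 3 of 100 splits reached the 13 called in mMDSC (highest other 14) and 15 of 100 the 9 called in gMDSC (highest other 15). The share in mMDSC lies under 0.05 but is not adjusted for the comparisons tested, and another split called more lists. With an estimated correlation 0 of these lists passed. Chance is therefore not excluded for the number of lists in either cell type. Splits other than the real one called a median of 4 lists in mMDSC, 5 in gMDSC and 4 for the difference. Fewer than 5 of 100 splits gave a p as small as the real one for the MHC class II, immediate-early, lysosome and epithelial lists in mMDSC (3, 3, 1 and 3), the hypoxia, MHC class II, cell cycle and epithelial lists in gMDSC (1, 1, 4 and 4) and the hypoxia and MHC class II lists for the difference (1 and 1). For the hypoxia list in gMDSC the lead was narrow, with an unadjusted camera p of 1.2e-18 against 2.58e-18 in another split. Between cell types, of the called lists, fewer than 5 splits gave so small a p for the STAT3, immediate-early, neutrophil and monocyte lists (1, 1, 1 and 3). The suppressive effectors list, which was not called, had 4 such splits. However, 16 splits matched the type I interferon list, 10 the MHC class II list, 10 the cell cycle list, 9 the cholesterol list and 6 the NF-kB list. For these 5, for the other lists called with CBPi and for every list of the difference, chance is not excluded this way.

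Of the genes named for the difference between cell types, log2 fold changes were larger in gMDSC by 3.99 for Fry, 3.96 for Hspa1a, 3.94 for Hspa1b, 3.81 for Nos2 and 3.73 for Thbs1. They differed by -6.47 for Oscp1, -3.55 for Egr3, -2.24 for Galnt12, -2.21 for Clec4n, -2.15 for Lrg1 and -1.49 for Cd74. The median difference of the MYC and ribosome biogenesis list was -0.29.

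Single libraries lay far from the other 4 of their group in 21 of 380 groups tested, where chance gives 19, each by a gap to the nearest library divided by the group's range. Vehicle gMDSC 5 stood apart in total counts (0.841; 23.27 M against at most 14.10) and Ly6g (0.723; 0.438 CPM). Vehicle gMDSC 3 stood apart in the cholesterol synthesis list (0.841), Krt80 (0.714), Egr3 (0.786) and Ccr2 (0.769), and vehicle gMDSC 4 in Ifna5 (1.00), where the other 4 had no counts. CBPi gMDSC 6 stood apart in the cell cycle list (0.789), Myc (0.823) and Ly6g (0.71), and CBPi gMDSC 9 in Galnt12 (0.840). Vehicle mMDSC 4 stood apart in the lysosome list (0.814), Trp53i11 (0.762), Lhfpl2 (0.813) and Ero1a (0.756), vehicle mMDSC 1 in Lrg1 (0.760) and vehicle mMDSC 2 in Chil1 (0.754). CBPi mMDSC 6 stood apart in Myc (0.741), CBPi mMDSC 7 in Trp53i11 (0.756), CBPi mMDSC 8 in the dendritic cell list (0.779) and CBPi mMDSC 9 in Rufy4 (0.914).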

How the results depend on the processing

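The thinned libraries and the fits without CBPi gMDSC 6 and 7 were chosen only after the results were seen. No named gene or list that passed the test in the main comparison or an alternative had opposite signs in the 2. Signs turned only among values that passed in neither, such as Arg1 in gMDSC (-0.05 to 0.63 with 1 library left out). Of 3627 values of named genes 3398 kept their side of the threshold, 221 lost and 8 gained a call, and of 1431 values of lists 1328 kept it, 74 lost and 29 gained one. The causes of the changes were not tested.

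The counts of changed genes in mMDSC (1020), in gMDSC (1135), for the difference (92) and in both cell types (377) were 1647, 1926, 277 and 629 with DESeq2. With limma the counts in mMDSC and in both were 1688 and 671. With all 20 libraries in the fit the counts in mMDSC and gMDSC were 639 and 2182, and the share of rises in mMDSC went from 35.3% to 25.8%. Without the libraries numbered 3 and 7 the counts in mMDSC, for the difference and in both were 534, 40 and 220. The covariate for neutrophil identity gave 571 in mMDSC. Without CBPi gMDSC 6 and 7, gMDSC had 306, the difference 36 and both 156.

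Without the filter Cd274 in mMDSC (adjusted p = 0.0561) and Itgam between cell types (0.0566) lost their calls. Without it the MHC class I, matrix, macrophage and neutrophil identity lists in gMDSC (0.0472, 0.0307, 0.0345 and 0.0479) and the matrix list in mMDSC (0.0495) passed. With fry the suppressive and matrix lists in mMDSC (0.042 and 0.0314) and the acetyltransferase list in gMDSC (0.0131) passed. With fry the NF-kB and granule lists in mMDSC (0.0945 and 0.0633), the MYC and lymphocyte lists in gMDSC (0.0943 and 0.0593) and the MHC class II and MYC lists for the difference (0.238 and 0.417) did not. With limma Ptprc and Adgre1 passed between cell types (0.00762 and 0.0361).

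With 1 library left out, counts ran from 694 to 1143 in mMDSC, 587 to 1394 in gMDSC, 34 to 111 for the difference, 2032 to 3270 between cell types and 251 to 432 in both. Lists past the test ran from 12 to 15 in mMDSC, 5 (without vehicle gMDSC 1) to 11 in gMDSC and 2 to 5 (without vehicle mMDSC 1) for the difference. With an estimated correlation 0 of the lists passed in mMDSC, gMDSC, the difference and between cell types, where the preset gave 13, 9, 3 and 9 and fry 13, 8, 1 and 14.

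The replicate number as a block gave 52 genes for the difference, 2014 between cell types and 2 lists for the difference. With the block the differences of Nos2 (adjusted p = 0.125) and Egr3 (0.087) and the MYC and ribosome list (0.103) did not pass, nor did Itgam between cell types (0.0639). Same-numbered libraries of the 2 cell types deviated together weakly at most: over 10 pairs the correlations were -0.031 to 0.168, with 2 over 0.1, and 7 of 20 libraries correlated best with their own number. Such values cannot show whether same-numbered libraries came from one mouse, so the calls lost with the block are not set aside.

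With libraries thinned to the smallest total the counts were 1005 in mMDSC, 1144 in gMDSC and 108 for the difference.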

Other observations

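The levels in this part were looked up only after the results were seen. RNA of macrophage genes was present in the gMDSC libraries although the gate excluded F4/80: in vehicle mice Apoe was at 32272 ± 13126 CPM in gMDSC and 17773 ± 3576 in mMDSC, C1qa at 3543 ± 1093 and 2093 ± 268, and Trem2 at 225 ± 78.1 and 89.4 ± 11.7 (n = 5 each). Adgre1, the gene of F4/80 itself, was at 1020 ± 330 CPM in gMDSC and 811 ± 80.3 in mMDSC, and Csf1r at 2108 ± 739 and 2241 ± 467. Other macrophage genes were lower in gMDSC, with Cd163 at 6.34% of its mMDSC level, Gpnmb at 23.5%, Folr2 at 34.1% and Fcgr1 at 51.4%. The list as a whole did not differ between cell types (6 higher and 7 lower of 25, median -0.01). Of the monocyte genes, F13a1 was in gMDSC at 1.10% of its mMDSC level, Vcan at 1.75% and Ly6c2 at 5.36%, while Cd14 was at 450.6%. The neutrophil genes Cxcr2, S100a8 and Mmp9 lay in mMDSC at 0.0898%, 0.457% and 0.346% of their gMDSC level. Other neutrophil genes lay closer, with Csf3r at 5.90%, Clec4e at 17.6% and Mmp8 at 59.3%, and Cd177 was higher in mMDSC (503.4%). The interferon genes Ifna4 and Ifna5 were at 77.3 ± 35.6 and 10.3 ± 8.12 CPM in vehicle mMDSC. The eosinophil marker Siglecf was higher in vehicle gMDSC than in mMDSC by 5.54 (adjusted p = 3.18e-05).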
